A study of Homo sapiens with 9 samples.

How the data were processed

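The 9 arrays comprised 3 from cells given scrambled siRNA, 3 from cells given Erk1 and Erk2 siRNA pair A and 3 from cells given the independent pair B, all sampled 4 days after electroporation. Per the labels, biotin-labelled total RNA was hybridised to one-colour Affymetrix arrays. The authors deposited a single intensity per probe set and array, and RMA (Robust Multi-array Average, which normalises between arrays) is named in the submitters' processing notes, with no version given in the sources used here. The deposited intensities are on a linear scale, between 11.2 and 29265 over all arrays, so log2 was taken here, with no pseudocount and no further normalisation. Arrays give no read depth, and the number of arrays and the brightness over background limit the precision.

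The table held 22277 probe sets. Of these 62 were controls, 19064 had 1 gene symbol, 1043 had several and 2108 had none in the platform annotation used here, and 19052 of the single-symbol probe sets matched the current human gene table by gene identifier. Control probe sets and those with several symbols or none were left out of the gene tests. XIST and Y-linked genes (31 probe sets) were left out of all tests. Each of the 11939 genes was represented by the probe set with the highest mean log2 value over all arrays, since 4304 genes had more than 1. Among these, 36 genes had probe sets called in opposite directions in the mean of pairs A and B against scrambled, none of them a gene named by the rule below. In single pairs this was not counted. Of the siRNA targets the annotation used here names MAPK3, and Erk2 was not analysed here.

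Groups came from the sample titles. A linear model of the 3 group means was fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The contrasts were the mean of pairs A and B minus scrambled, A minus scrambled, B minus scrambled and A minus B. P-values were adjusted over all genes by Benjamini-Hochberg, and genes under 0.05 were called changed. Adjusted p-values of single genes come from limma, fold changes are on the log2 scale, and SE is the moderated standard error of limma. The labels describe biological replicates.

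The 26 gene lists (620 genes, 549 tested) and the rule for named genes were fixed before the data were examined. Lists covered MAPK cascade components, ERK outputs, immediate early genes, EGF receptor ligands, the cell cycle, DNA repair, p53 targets, apoptosis, keratinocyte differentiation, basal and activated states, inflammation, interferon, matrix proteases, cholesterol, glycolysis, ribosome biogenesis, stress, housekeeping genes and markers of melanocytes, fibroblasts, immune, endothelial and Merkel cells. They were tested with camera of limma with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation and fry, which asks whether genes of a list move one way on balance without comparing them with other genes, were alternatives. Counts adjusted over the list alone repeat the adjustment within the list. The named genes were MAPK3, the 12 genes that rose most and the 12 that fell most among genes passing with both pairs in one direction, up to 4 members per list with the largest change that passed, the fixed names CCNB1, CDK1, CCNA2, FOS, FOSL1, EGR1, DUSP6, MYC and CCND1 whatever their values, and the 5 highest and 5 lowest genes of A minus B. A further 17 genes were named after their values were seen, and are marked so in the report or belong to the closing section.

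The steps were tested on simulated data made from the real values with known changes in 50 genes at each size, among 11939. For both pairs against scrambled the fit recovered 68.0% of genes changed by 0.3 on the log2 scale, 98.0% at 0.6 and 100% at 1 and 2, and 5.18% of calls were false. For A minus B it recovered 36.0% at 0.3, 98.0% at 0.6 and 100% at 1 and 2. The noise was independent for each gene, so none of these rates covers deviations shared by a whole array. Because both pairs shared the scrambled arrays, 100 sets of unchanged groups against shared controls were simulated for the correlation and overlap of their effects. This was done once with independent noise per gene and once by resampling, with replacement, the deviations of whole arrays from their group means. With resampled deviations the unchanged groups gave a mean of 15.94 called genes with A and 63.17 with B. The highest counts were 912 and 2992, from draws in which a group could hold the same array more than once.

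Alternatives were the mean or the most variable probe set per gene, the dimmest 40% of genes left out, cyclic loess, 75th percentile centring and repeated quantile normalisation, trended and robust moderation, array weights, only the groups compared, the replicate number as a fixed or random block, each array left out, an adjusted p of 0.01, a 2-fold floor and a treat test against a fold of 1.2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.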

Results

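RNA levels were measured in primary human keratinocytes, the main cell type of the epidermis grown from tissue, 4 days after electroporation with small interfering RNAs (siRNAs). The study compared 3 groups of 3 biological replicates each. Control cells received a scrambled siRNA, and the other groups received pair A or pair B, independent siRNA pairs that each target the MAP kinases Erk1 and Erk2. The comparisons ask which genes respond to loss of both kinases, and whether the independent pairs give a like response. Each of the 9 samples was hybridised to its own one-colour array of 22277 probe sets, and 11939 genes were tested. The median intensity lay between 127 and 136 on every array, and the number of arrays limits the precision. Scrambled replicate 2 stood apart from the other controls: the SD of its deviation from the group mean was 0.20 on the log2 scale, against 0.08 to 0.13 on the remaining arrays.

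Of the 2 kinases targeted, only Erk1 is reported, and Erk2 was not analysed here. MAPK3, which encodes Erk1 and lies on chromosome 16, fell with both siRNA pairs. Its log2 intensity was 8.03 ± 0.14 (SD, n = 3) in scrambled cells, 7.24 ± 0.11 (SD, n = 3) with pair A and 7.25 ± 0.12 (SD, n = 3) with pair B. These are 1.72-fold and 1.71-fold decreases, with adjusted p-values of 1.1e-04 and 6.0e-05. All 6 Erk siRNA arrays, at 7.11 to 7.34, lay below the 3 scrambled arrays, at 7.87 to 8.13. A difference between the pairs did not pass for MAPK3, with a log2 difference of -0.01 (SE 0.09) and an adjusted p of 0.97. MAPK3 was read by a single probe set, of a class whose probes can also match related transcripts.

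**Figure D1:**
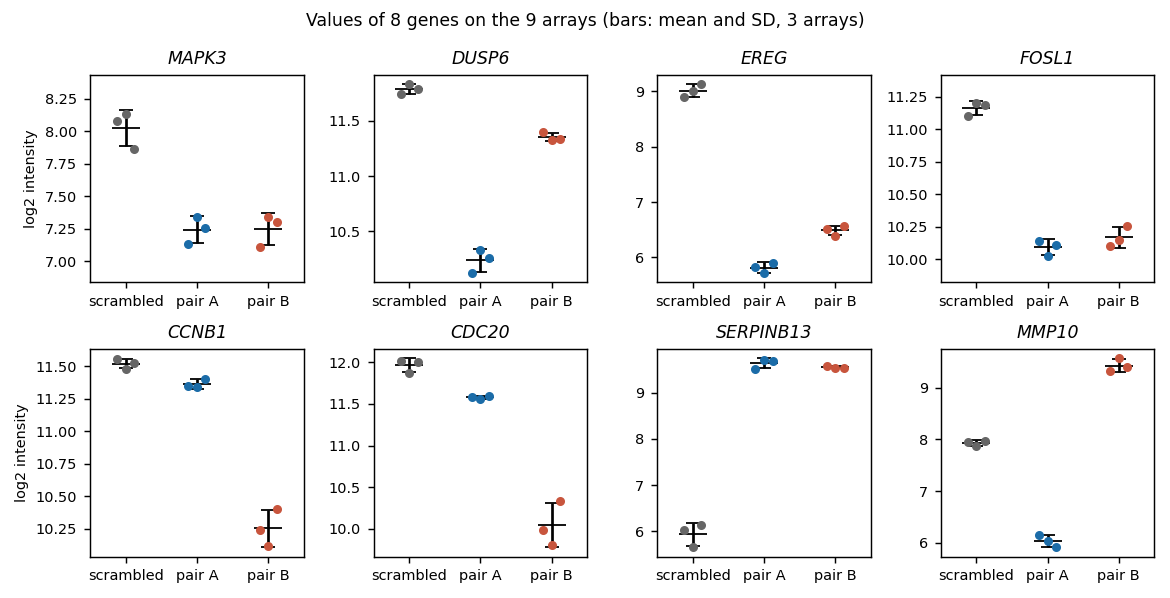
Log2 intensity (vertical axis) of 8 genes on each of the 9 arrays by siRNA group (horizontal axis), with points for arrays and bars for the mean and SD of 3 arrays. MAPK3 lies at 7.11 to 7.34 in the 6 Erk siRNA arrays, CCNB1 lies near 11.36 with pair A but near 10.25 with pair B, and MMP10 lies below scrambled with pair A and above it with pair B.

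The effect of Erk depletion was first taken over both siRNA pairs against scrambled. The genes that rose most included NEFL, a neuronal intermediate filament gene, with a log2 fold change of 4.15 (SE 0.12), TAGLN, an actin-binding protein of smooth muscle, at 3.91 (SE 0.09), and the squamous serpin SERPINB13 at 3.65 (SE 0.09). CLDN1, a tight junction gene, rose by 3.09 and ID3, a target of BMP signalling, by 2.88. The genes that fell most included the collagenase MMP1 at -3.58 (SE 0.10), the chloride channel ANO1 at -3.31 (SE 0.08), G0S2 at -3.25 and the EGF receptor ligand EREG at -2.86. The other genes among the 12 that rose most were CALML3, IL32, KRT13, TNFSF10, ZNF750, ACKR3 and CLIC3, at 2.41 to 2.85. The other genes among the 12 that fell most were SCG5, PLAT, TFPI2, CYP27B1, AXL, EGR1, CIDEA and HS3ST2, at -2.58 to -1.98. These 24 genes were taken only from genes that passed the adjusted p of 0.05 with both pairs in a single direction, so that passing is no separate result.

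In total 4636 of the 11939 genes changed, of which 2548 rose and 2088 fell, and 258 changed at least 2-fold (172 up and 86 down). Without scrambled replicate 2 the count was 4551, with 2340 up and 2211 down. With arrays centred on the 75th percentile 2237 rose and 2480 fell, so which direction held more genes depended on the scaling. The contrast averages pairs A and B, so a single pair can carry a call, here and in the list results over both pairs. Genes called in the same direction with each pair alone numbered 2291, with 1405 up and 886 down. The scrambled intensities of NEFL, ZNF750, ACKR3, EGF, DEFB1, CXCL8 and CXCL14 (20.6 to 44.1), and those of CXCL5 with Erk siRNA (18.8 to 28.2), lay near or under the 25th percentile of an array (37.4 to 40.1), so the sizes of their fold changes are uncertain. The same holds for the fall of ANO1, whose intensities with pair A were 33.3 to 41.1.

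Cell cycle genes fell as groups. All 49 measured members of the G2 and mitosis list fell, with a median log2 fold change of -0.71 (adjusted p = 2.8e-24, camera; adjusted p = 0.12 with an estimated correlation). KIF14, a mitotic kinesin, fell by 1.19, CDC20, an activator of the anaphase-promoting complex, by 1.16, CENPE by 1.05 and CEP55 by 1.01. CCNB1, the mitotic cyclin B1, was at -0.71, CDK1 at -0.56 and CCNA2 at -0.84, each past the threshold over both pairs. With pair A alone CCNB1, CDK1, CCNA2 and CENPE did not pass. Of 42 G1/S and DNA replication genes 35 fell and none rose, with a median of -0.49 (adjusted p = 2.0e-16; adjusted p = 0.12 with an estimated correlation). CDC6, MCM10, CDC25A and CDC45 fell by 1.06, 1.04, 1.02 and 0.96. Of 19 DNA repair genes 15 fell and none rose, with a median of -0.37 (adjusted p = 6.3e-07; adjusted p = 0.12 with an estimated correlation), led by BLM at -0.85 and FANCG at -0.83. Adjusted over the list alone, 49 G2 and mitosis, 35 G1/S and 17 DNA repair genes fell. A sign of RNA quality, the 3 prime minus 5 prime log2 difference of control probe sets, also differed for GAPDH. It was higher on all Erk siRNA arrays (-0.0068 to 0.0489) than on the scrambled arrays (-0.0256 to -0.0155). For ACTB pair A (-0.1102 to -0.0809) did not lie above scrambled (-0.0809 to -0.0545), while pair B did (-0.0054 to 0.0643).

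Of 16 p53 target genes 13 rose and none fell, with a median of 0.72 (adjusted p = 1.6e-08; adjusted p = 0.10 with an estimated correlation). SESN1 rose by 1.72, MDM2, a p53 inhibitor that p53 itself induces, by 1.53, ZMAT3 by 1.04 and PPM1D by 0.97. Among 18 CDK inhibitors and pocket protein genes 11 rose and 4 fell, which did not pass as a list (adjusted p = 0.098). CDKN1B, which encodes the CDK inhibitor p27, rose by 0.98, GADD45A by 0.81 and CDKN2B by 0.70, while CCNG2 fell by 0.79. Of 20 apoptosis regulators 8 rose and 4 fell, with no list call (adjusted p = 0.20), and BIK was at 0.55 and BAX at 0.51. Counts adjusted over the list alone were as follows: 13 p53 targets rose, 11 CDK inhibitor genes rose and 5 fell, and 8 apoptosis regulators rose and 5 fell.

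Epidermal differentiation genes rose. Of 38 keratinocyte terminal differentiation genes 24 rose and none fell, with a median of 0.43 (adjusted p = 8.1e-10; adjusted p = 0.10 with an estimated correlation). CALML3 rose by 2.85, ZNF750, a transcription factor of late differentiation, by 2.47, CLIC3 by 2.41 and the lipid transporter ABCA12 by 1.92. The cornified envelope genes IVL and SPRR3 and the transcription factor KLF4, named after their values were seen, rose by 1.40, 1.84 and 1.50. Of 16 activated keratinocyte and barrier alarm genes 12 rose and 1 fell, with a median of 0.60 (adjusted p = 5.8e-05; adjusted p = 0.12 with an estimated correlation). S100A8, S100A9 and DEFB1 were at 1.94, 1.33 and 1.33, and SERPINB1 fell by 1.39. The 19 basal keratinocyte genes went both ways, with 5 up and 7 down (adjusted p = 0.775). The hemidesmosome genes PLEC, ITGA6 and DST went both ways, at -0.81, -0.69 and 1.02, and POSTN rose by 1.33. Adjusted over the list alone, 24 terminal differentiation genes rose, 13 activated keratinocyte genes rose and 1 fell, and 5 basal genes rose and 7 fell.

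Genes of the MAP kinase pathway changed in both directions. Of 21 ERK output and feedback genes 10 fell and 4 rose, with a median of -0.15 (adjusted p = 0.017; adjusted p = 0.12 with an estimated correlation). DUSP5 and DUSP6, which encode ERK phosphatases, fell by 1.22 and 0.99, IER3 by 0.97 and PHLDA1 by 0.71. DUSP4, another ERK phosphatase gene named after its values were seen, fell by 0.78 with pair A and rose by 0.47 with pair B. With the mean of its probe sets the rise with pair B was 0.16 and did not pass (adjusted p = 0.059). Over both pairs that mean was at -0.31 (adjusted p = 0.0012). CCND1 was at -0.26 (adjusted p = 0.00755). With pair A alone CCND1 did not pass (adjusted p = 0.0510). It did pass with cyclic loess (adjusted p = 0.0267), 75th percentile centring (0.0243) and array weights (0.00479), among other alternatives. Under each of 3 other normalizations 2 and not 4 of the ERK output genes rose, and 10 or 11 fell. Of 19 immediate early and AP-1 genes 6 fell and 7 rose (adjusted p = 0.94). EGR1, FOS and FOSL1 fell by 2.10, 1.77 and 1.03, and ATF3 and FOSL2 rose by 2.29 and 1.06. MYC was at -0.10 and did not pass (adjusted p = 0.10), though it passed in 3 alternatives, with an adjusted p down to 0.0174 with array weights. Of 6 EGF receptor ligands 3 fell and 1 rose (adjusted p = 0.099): EREG, HBEGF and TGFA fell by 2.86, 0.94 and 0.42, and EGF rose by 1.15. Of 24 MAPK cascade components 7 fell and 5 rose (adjusted p = 0.447), among them MAP2K1, which encodes the ERK kinase MEK1, at -0.92, and the exchange factors SOS2 and SOS1 at 0.75 and 0.59. Counts adjusted over the list alone were as follows: 11 ERK output genes fell and 4 rose, 6 immediate early genes fell and 8 rose, 3 ligands fell and 1 rose, and 10 cascade genes fell and 6 rose.

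Of 18 cholesterol synthesis genes 13 fell and 1 rose, with a median of -0.45 (adjusted p = 8.7e-07; adjusted p = 0.12 with an estimated correlation). INSIG1, HMGCS1 and ACAT2 fell by 1.36, 1.35 and 0.97. Of 21 ribosome biogenesis and MYC target genes 15 fell and none rose, with a median of -0.26 (adjusted p = 1.2e-05; adjusted p = 0.10 with an estimated correlation), and RRP9 and ODC1 were at -0.66 and -0.45. Glycolysis and hypoxia genes (11 of 26 down and 4 up, adjusted p = 0.18) and unfolded protein and amino acid stress genes (8 of 22 down and 4 up, adjusted p = 0.325) did not pass as lists. VEGFA fell by 0.68 while ADM and SLC2A1 rose by 1.10 and 0.67. Adjusted over the list alone, 14 cholesterol genes fell and 1 rose, 15 ribosome genes fell, 12 glycolysis genes fell and 4 rose, and 8 stress genes fell and 4 rose.

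Secreted and immune genes went both ways. Of 26 inflammatory cytokine and NF-kB target genes 12 rose and 6 fell (adjusted p = 0.18), with CXCL8 at 1.96, NFKBIA at 0.94 and CXCL5 at -0.89. Of 40 interferon-stimulated genes 8 rose and 10 fell (adjusted p = 0.855), with RSAD2 at 1.18, TRIM22 at 0.96 and ISG20 at -1.64. Of 25 matrix protease and migration genes 10 rose and 10 fell (adjusted p = 0.94): MMP9 and TNC rose by 2.17 and 2.01, and MMP1 and PLAT fell by 3.58 and 2.57. Counts adjusted over the list alone were as follows: 14 inflammatory genes rose and 7 fell, 8 interferon-stimulated genes rose and 10 fell, and 10 matrix genes rose and 10 fell.

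Markers of other cell types were read for cells that such cultures can hold. Of 12 melanocyte markers 5 rose and none fell, with a median of 0.20 (adjusted p = 0.018; adjusted p = 0.33 with an estimated correlation), led by TYRP1 at 0.70 and MLANA at 0.62. That call was lost when the dimmest 40% of genes were left out (adjusted p = 0.13). Of 19 fibroblast markers 6 rose, COL5A1 by 1.15 and MMP2 by 0.86, and 1 fell, with no list call (adjusted p = 0.465). VIM was at -0.56 over both pairs, but at -1.11 with pair A and -0.02 with pair B, where it did not pass (adjusted p = 0.855). None of the 16 immune cell markers passed (adjusted p = 0.67). Of 9 endothelial markers only ENG, at -0.24, passed (adjusted p = 0.78 for the list), and of 9 Merkel cell markers only ENO2, at -0.23 (adjusted p = 0.28 for the list). With pair B alone ENG did not pass (adjusted p = 0.103), and ENO2 passed with neither pair alone (adjusted p = 0.0767 and 0.0582). ENO2 did pass with pair A and with pair B under 75th percentile centring (adjusted p = 0.0177 and 0.0150). It also did so with array weights and without scrambled replicate 2 (adjusted p = 0.0037 and 0.0025 for the latter). The ENO2 call over both pairs was lost in 7 of the 9 fits without a single array, with an adjusted p of up to 0.141. Of 13 housekeeping genes 2 rose and 3 fell (adjusted p = 0.39), the largest change being GUSB at -0.59, and 5 fell with cyclic loess. Adjusted over the list alone, 5 melanocyte markers rose, 6 fibroblast markers rose and 1 fell, 0 immune and 0 Merkel markers passed, 1 endothelial marker fell, and 2 housekeeping genes rose and 3 fell.

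The tests above used limma on all 9 arrays and camera with a preset correlation on 26 lists. In this comparison 10 lists passed with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.10. List median and mean differed in sign for matrix proteases (0.07 and -0.08), fibroblast markers (-0.01 and 0.12), unfolded protein genes (-0.03 and 0.01), immediate early genes (0.0045 and -0.0201) and basal genes (-0.0011 and 0.0021), none of which passed.

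**Figure D2:**
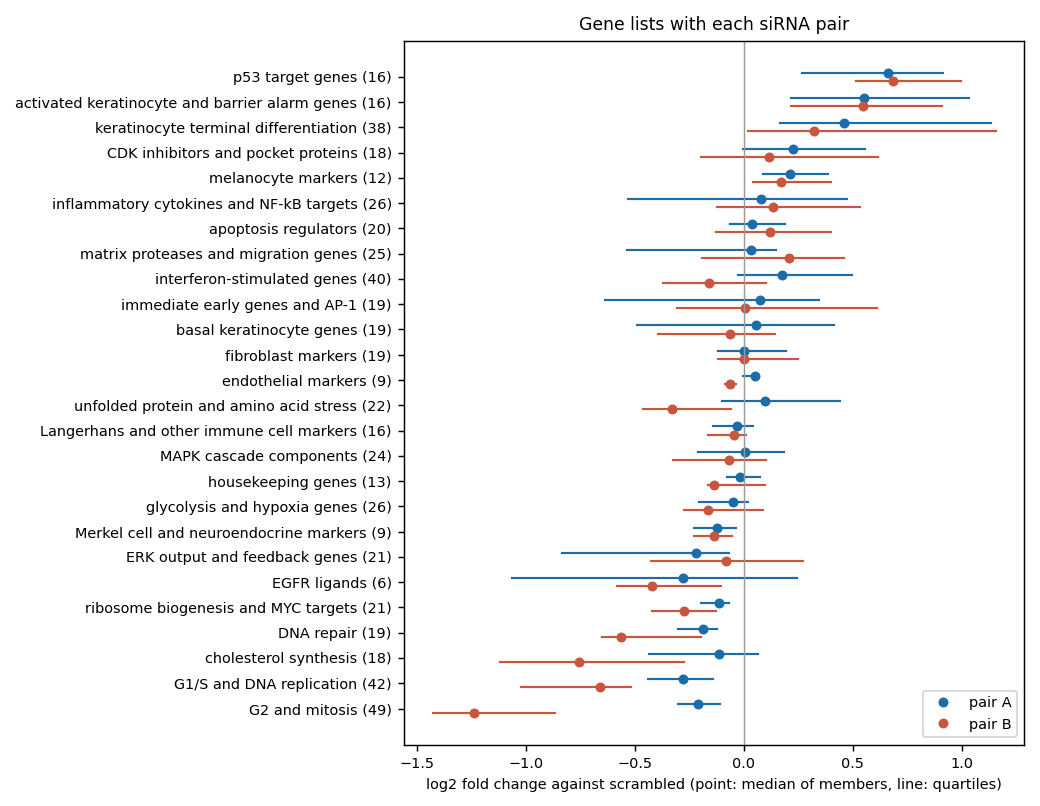
Log2 fold change against scrambled (horizontal axis) of the members of 26 gene lists (vertical axis, number of measured genes in brackets) with pair A (blue) and pair B (red), as medians with lines that join the quartiles. The G2 and mitosis list has a median of -0.21 with pair A and -1.24 with pair B, and the p53 target list has medians of 0.66 and 0.68.

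With pair A alone, MMP1 fell by 5.20 and ANO1 by 3.65, and NEFL and TAGLN rose by 4.16 and 3.75. KRT13 and KRT4, a keratin pair of mucosal epithelia, rose by 3.83 and 3.14. Of 38 terminal differentiation genes 25 rose and none fell (27 rose adjusted over the list alone), with a median of 0.46 (adjusted p = 6.2e-12; adjusted p = 0.054 with an estimated correlation). Of 21 ERK output genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 1.2e-05; adjusted p = 0.054 with an estimated correlation), and DUSP6 fell by 1.55. Of 49 G2 and mitosis genes 22 fell and none rose (26 fell adjusted over the list alone), with a median of -0.21 (adjusted p = 2.9e-08; adjusted p = 0.39 with an estimated correlation). The 3 prime minus 5 prime log2 difference for GAPDH was also higher with pair A (-0.0068 to 0.0050) than on the scrambled arrays (-0.0256 to -0.0155). That for ACTB was not. CCNB1 and CDK1 were at -0.16 and -0.19 with pair A and did not pass (adjusted p = 0.13 and 0.085). CDK1 with pair A passed in 6 alternatives, among them without scrambled replicate 2 (adjusted p = 0.0339), and CCNB1 with array weights (adjusted p = 0.0353). CENPE and CCNA2 were at -0.51 and -0.11 with pair A and did not pass (adjusted p = 0.0785 and 0.544). CENPE did pass in some alternatives, among them array weights (adjusted p = 0.0215), repeated quantile normalisation (0.0427) and without scrambled replicate 2 (0.0475). In all 3361 genes changed with pair A, 1985 up and 1376 down. With arrays centred on the 75th percentile the split was 1669 up and 1782 down, so the balance of directions depended on the scaling. In this comparison 12 lists passed with the preset correlation and 0 with an estimated correlation.

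With pair B alone, NEFL and TAGLN rose by 4.13 and 4.06, SERPINB13 by 3.61 and CLDN1 by 3.35. G0S2 fell by 3.20, ANO1 by 2.97 and TFPI2 by 2.61. All 49 G2 and mitosis genes fell (49 adjusted over the list alone), with a median of -1.24 (adjusted p = 1.4e-27; adjusted p = 0.14 with an estimated correlation), CDC20 by 1.92 and CCNB1 by 1.27. The 3 prime minus 5 prime log2 difference of control probe sets, a sign of RNA quality, was also higher on the pair B arrays (-0.0054 to 0.0643 for ACTB and 0.0207 to 0.0489 for GAPDH) than on the scrambled arrays (-0.0809 to -0.0545 and -0.0256 to -0.0155). Of 18 cholesterol synthesis genes 16 fell (16 adjusted over the list alone), with a median of -0.75 (adjusted p = 1.1e-08; adjusted p = 0.14 with an estimated correlation). Of 38 terminal differentiation genes 23 rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 0.32 (adjusted p = 3.2e-06; adjusted p = 0.14 with an estimated correlation). Of 21 ERK output genes 9 fell and 6 rose (9 and 6 adjusted over the list alone), with a median of -0.08 and no list call (adjusted p = 0.36). In all 5148 genes changed with pair B, 2815 up and 2333 down, and 9 lists passed with the preset correlation and 0 with an estimated correlation. With 75th percentile centring 2577 rose and 2622 fell with pair B.

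Genes changed the same way by both pairs included NEFL, TAGLN, SERPINB13 and ID3 among those that rose and G0S2, CYP27B1, AXL and FOSL1 among those that fell. ID3 was at 2.89 with pair A and 2.88 with pair B, and CYP27B1 at -2.23 and -2.18. In all 2291 genes changed the same way, 1405 up and 886 down, and 256 changed opposite ways (136 up with A and down with B, 120 the reverse). At least 2-fold with each pair, 99 rose and 46 fell. Lists drawn independently would share 737 genes the same way (468 up and 269 down), and simulated unchanged groups against the same controls gave at most 1, or at most 107 when whole-array deviations were resampled. Across genes, which are not independent replicates, the fold changes of the pairs correlated with r = 0.668 (Spearman 0.619), against a mean of 0.501 for simulated unchanged groups. With resampled deviations the mean was 0.508 and the highest 0.982, above the observed value. These deviations were drawn with replacement, so a group could hold the same array more than once, unlike the real groups. The highest value therefore cannot decide whether r lies beyond what unchanged groups can give. The covariance was 0.102 against a mean of 0.00353 simulated, and at most 0.0307 with resampled deviations. The 3 scrambled arrays served both comparisons and are too few to split, so part of the excess may come from the shared controls.

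**Figure D3:**
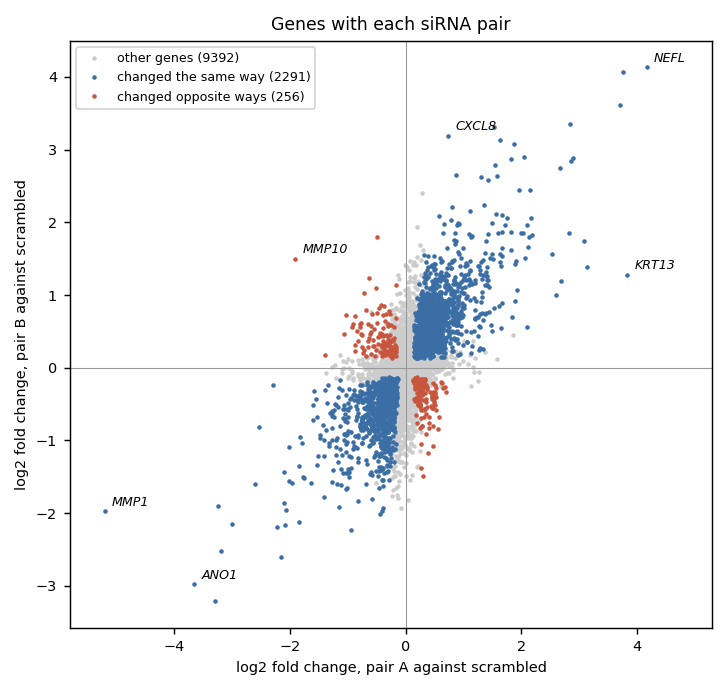
Log2 fold change against scrambled with pair A (horizontal axis) and pair B (vertical axis), a point per gene: blue for the 2291 genes changed the same way, red for the 256 changed opposite ways and grey for the others. NEFL lies at 4.16 and 4.13, and MMP10 at -1.90 and 1.50.

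The direct comparison of pair A with pair B tested where the reagents differed. The genes highest with pair A relative to pair B were KRT13, with a log2 difference of 2.55 (SE 0.28), the mitotic kinesin KIF20A at 1.86 (SE 0.11), ASL, a urea cycle enzyme, at 1.84, LYRM1 at 1.80 and KRT4 at 1.76. The genes lowest with pair A were the stromelysin MMP10 at -3.40 (SE 0.08), MMP1 at -3.23 (SE 0.12), CXCL8 at -2.46, KYNU at -2.28 and CXCL14 at -2.12. MMP10 fell by 1.90 with pair A and rose by 1.50 with pair B. In all 3964 genes differed, 2021 higher and 1943 lower with pair A, and 236 differed at least 2-fold.

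Of 49 G2 and mitosis genes 48 were higher with pair A than with pair B (49 adjusted over the list alone), with a median difference of 0.98 (adjusted p = 5.7e-29; adjusted p = 0.11 with an estimated correlation). CDC20, CCNA2 and CCNB1 differed by 1.54, 1.45 and 1.11. A sign of RNA quality, the 3 prime minus 5 prime log2 difference of control probe sets, also separated these groups: for ACTB it was -0.11 to -0.08 with pair A and -0.0054 to 0.0643 with pair B, and for GAPDH -0.0068 to 0.0050 and 0.0207 to 0.0489. Of 42 G1/S genes 32 were higher and 4 lower (33 and 4 adjusted over the list alone; adjusted p = 2.6e-09, and adjusted p = 0.28 with an estimated correlation). DNA repair genes were higher with pair A for 11 of 19 and lower for 1 (12 and 2 adjusted over the list alone; adjusted p = 4.1e-04, and adjusted p = 0.27 with an estimated correlation). Of 18 cholesterol synthesis genes 16 were higher and none lower (17 higher adjusted over the list alone; adjusted p = 2.9e-09, and adjusted p = 0.11 with an estimated correlation), with ACAT2 at 0.92. Of 21 ribosome biogenesis genes 9 were higher (9 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.27 with an estimated correlation).

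Stress and interferon genes were also higher with pair A. Of 22 unfolded protein and amino acid stress genes 16 were higher and 2 lower (16 and 3 adjusted over the list alone), with a median difference of 0.52 (adjusted p = 5.7e-07; adjusted p = 0.095 with an estimated correlation). With pair B against scrambled 14 of these stress genes fell and 2 rose (adjusted p = 9.97e-04; adjusted p = 0.15 with an estimated correlation). With pair A against scrambled 10 rose and 4 fell, which did not pass as a list (adjusted p = 0.075). EDEM1 differed by 0.98 and TRIB3 by 0.70, and the amino acid synthesis genes ASNS and PSAT1, named after their values were seen, by 0.88 and 0.84. Of 40 interferon-stimulated genes 24 were higher and 4 lower (25 and 5 adjusted over the list alone), with a median difference of 0.37 (adjusted p = 9.7e-07; adjusted p = 0.46 with an estimated correlation). Against scrambled, 20 of them rose and 4 fell with pair A (adjusted p = 0.0027; adjusted p = 0.56 with an estimated correlation), and 7 rose and 17 fell with pair B (adjusted p = 0.084). The list passed as lower with pair B without scrambled replicate 2 (adjusted p = 0.024), without pair B replicate 3 (0.020), without the dimmest 40% of genes (0.016), with cyclic loess (0.039) and with array weights (0.030). For pair B it had an adjusted p = 0.646 with an estimated correlation. The 3 prime minus 5 prime difference for ACTB, -0.11 to -0.08 with pair A and -0.0054 to 0.0643 with pair B, separated the same arrays for every list compared between the pairs.

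Targets of ERK signalling were lower with pair A than with pair B. Of 21 ERK output genes 12 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median difference of -0.19 (adjusted p = 1.9e-04; adjusted p = 0.095 with an estimated correlation). DUSP6, PHLDA1 and DUSP5 differed by -1.11, -0.86 and -0.52. For PHLDA1 with pair B the sign depended on the probe set, at -0.28 with the brightest and 0.34 with the most variable. Of 19 immediate early genes 9 were lower and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0050, and adjusted p = 0.18 with an estimated correlation), with EGR1 at -0.996 and FOS at -0.66. Of 25 matrix protease genes 13 were lower and 4 higher (13 and 4 adjusted over the list alone; adjusted p = 1.9e-04, and adjusted p = 0.095 with an estimated correlation), with PLAT at -1.33 and MMP9 at -1.24. The remaining 16 lists did not pass between the pairs with camera, among them the p53 targets (adjusted p = 0.605) and terminal differentiation genes (adjusted p = 0.319). The housekeeping gene GUSB was at -1.36 with pair B and 0.19 with pair A, and did not pass with pair A (adjusted p = 0.13).

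**Figure D4:**
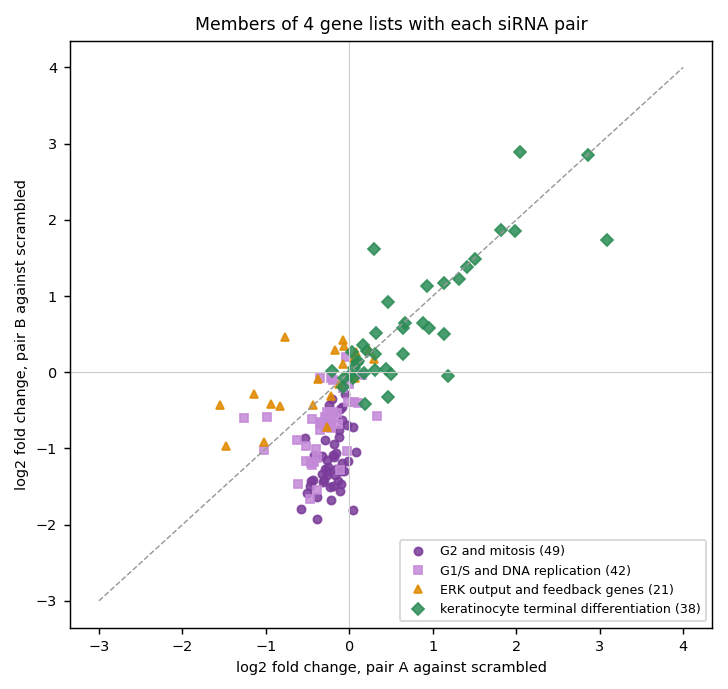
Log2 fold change against scrambled with pair A (horizontal axis) and pair B (vertical axis) for the members of 4 gene lists, a point per gene, with the line of equal change dashed. The 49 G2 and mitosis genes lie below that line, at medians of -0.21 and -1.24, and 12 of the 21 ERK output genes were lower with pair A.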

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

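The tests of the cell cycle and interferon patterns, and of RNA degradation and Erk depletion in scrambled replicate 2, were chosen only after the results were seen. The tests of intensity-dependent scaling and of the splits of the arrays were chosen before.

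G2 and mitosis genes fell further with siRNA pair B, with a median A minus B log2 difference of 0.98 (adjusted p = 0.11 with an estimated correlation). A stronger loss of the targets with pair B as the whole cause is argued against by the ERK output genes, which were lower with pair A (median difference -0.19; adjusted p = 0.095 with an estimated correlation), and by MAPK3, which differed by -0.01. The smallest median under 3 other normalizations was 0.97, so further scaling did not remove the difference. These normalizations started from values already normalized before deposit, so an effect of that earlier step was not tested. Off-target effects of a single pair may contribute and stay open: 256 genes changed opposite ways with the pairs, but no siRNA sequence was used here to assign them to a pair. Differences in Erk2 loss were not tested, nor was RNA quality, whose 3 prime minus 5 prime log2 difference for ACTB also separated pair A (-0.11 to -0.08) from pair B (-0.0054 to 0.0643).

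Interferon-stimulated genes were higher with pair A than with pair B, with a median difference of 0.37 (adjusted p = 0.46 with an estimated correlation). The smallest median under 3 other normalizations was 0.36, so further scaling did not remove this difference. An effect of the normalization made before deposit was not tested. Immune cells in the cultures stay open: the upper quartile of the same difference over the immune cell marker list was 0.071, but 0 of its 16 members were brighter than the median gene, the brightest being CD74, CD79A and CD1C at log2 intensities of 6.22, 6.14 and 6.01 in scrambled cells. An interferon response to pair A may contribute and stays open, since the rise against scrambled had an adjusted p of 0.562 with an estimated correlation and the list had a median of -0.16 with pair B, which did not pass (adjusted p = 0.0840) but passed in 5 alternatives (adjusted p of 0.016 to 0.039), with an adjusted p = 0.646 with an estimated correlation. RNA quality was not tested here either, and its ACTB difference separated the same arrays (-0.11 to -0.08 with pair A, -0.0054 to 0.0643 with pair B).

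Scrambled replicate 2 lay apart from the other scrambled arrays, with an SD of its deviation from the group mean of 0.20 on the log2 scale. Intensity-dependent scaling as the whole cause is argued against by the SD of 0.18 left after cyclic loess, above the highest of the other arrays, 0.12. Strong RNA degradation is argued against by an excess of at most 0.0183 in the 3 prime minus 5 prime log2 difference of control probe sets. For ACTB this array had the highest value of the scrambled arrays (-0.0545 against -0.0809 and -0.0728), and for GAPDH the lowest (-0.0256). A small difference in RNA quality lay under the bound of this test and stays open. An Erk-depleted culture is argued against by its MAPK3 log2 value of 8.13. No other biological explanation was tested.

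Other splits of the 9 arrays into 3 groups of 3 were drawn, 100 with the real one. The counts of splits with as many in this paragraph include the real split. For genes changed in the mean of both pairs against scrambled chance is argued against: only the real split gave a count as large (4636 against at most 2343). The same held for genes changed the same way (2291 against at most 1241). Not all possible splits were drawn, and the other splits still hold arrays of different groups, so chance is not excluded outright. For the 10 lists called in the mean of both pairs 9 splits gave as many and the highest other gave 12. Those splits also hold differences between the siRNA groups, so this test cannot decide, and chance is neither excluded nor shown for the lists. For single pairs and for A against B the 10 splits are too few: the real and highest other values were 3361 and 0 genes and 12 and 9 lists for pair A, 5148 and 0 genes and 9 and 10 lists for pair B (4 splits as many), and 3964 and 0 genes and 10 and 10 lists for A against B (2 splits as many).

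The results below differed between the pairs in the direct test and are given as the A minus B log2 difference. Other lists that differed had medians of 0.41 for G1/S and DNA replication, 0.33 for DNA repair, 0.57 for cholesterol synthesis, 0.13 for ribosome biogenesis, 0.52 for unfolded protein and amino acid stress, -0.29 for immediate early genes and -0.19 for matrix proteases. With an estimated correlation none of these 7 lists passed, with adjusted p-values of 0.28, 0.27, 0.11, 0.27, 0.095, 0.18 and 0.095 in that order. Among mitotic genes the differences were KIF14 1.22, CDC20 1.54, CENPE 1.08, CEP55 1.24, KIF20A 1.86, CCNB1 1.11, CDK1 0.75 and CCNA2 1.45. For replication and repair genes they were CDC6 1.19, MCM10 0.84, CDC45 1.15, FANCG 1.02, CHEK1 0.33 and PARP1 0.48. Growth arrest and apoptosis genes gave CDKN1B -0.32, CCNG2 -1.11, ZMAT3 -0.22, PPM1D 0.56, CASP8 -0.54 and TNFSF10 -1.21. ERK pathway, immediate early and ligand genes gave SOS2 -0.82, DUSP4 -1.25, DUSP5 -0.52, DUSP6 -1.11, PHLDA1 -0.86, EGR1 -0.996, FOS -0.66, MYC 0.18, HBEGF -0.65 and EREG -0.67. Keratinocyte genes gave KRT13 2.55, KRT4 1.76, ZNF750 -0.85, CLIC3 1.35, S100A8 1.50, S100A9 1.54, SERPINB1 -0.87, POSTN -1.52, DST -0.37 and ITGA6 -0.34. Inflammatory and interferon genes gave CXCL8 -2.46, CXCL14 -2.12, NFKBIA 0.51, KYNU -2.28, RSAD2 0.71, TRIM22 0.53, MX2 1.02 and ISG15 0.95. Matrix and mesenchymal genes gave MMP1 -3.23, MMP9 -1.24, MMP10 -3.40, PLAT -1.33, TNC -1.16, MMP2 -0.72, FBN1 -1.33 and VIM -1.09. Metabolic and biosynthetic genes gave INSIG1 0.50, HMGCS1 0.64, MVD 0.66, ACAT2 0.92, ADM -0.23, PFKFB3 -0.62, RRP9 0.49, SRM 0.37 and NOP2 0.50. Stress genes gave HERPUD1 0.47, EDEM1 0.98, TRIB3 0.70, ASNS 0.88 and PSAT1 0.84. Contractile, junction and signalling genes gave TAGLN -0.31, MYLK 0.47, TPM1 0.28, CLDN1 -0.50, CLDN4 -0.25, OCLN 0.33, BCL6 -0.38, PIK3IP1 -0.66 and SMAD7 -0.32. The remaining genes gave ACKR3 -1.77, ANO1 -0.67, SCG5 -0.84, TFPI2 0.46, HS3ST2 0.27, GPR143 0.21, ASL 1.84, LYRM1 1.80, GUSB 1.55, TFRC -0.62 and GAPDH 0.15. With single arrays left out, 9 of these calls were lost, with adjusted p-values of up to 0.161 for TAGLN, 0.143 for ZMAT3, 0.115 for PPM1D, 0.121 for GPR143, 0.0906 for GAPDH, 0.0842 for CDKN1B, 0.0939 for MYC, 0.164 for CLDN4 and 0.136 for OCLN. The TPM1 difference was 0.03 with its most variable probe set and did not pass (adjusted p = 0.841).

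Probe sets outside the gene tests also changed. Of 2108 probe sets with no gene symbol 381 changed in the mean of both pairs, 191 up and 190 down, and of 1043 with several symbols 291 changed, 166 up and 125 down.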

How the results depend on the processing

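All alternatives below were chosen before the data were examined. The total counts of genes stayed within 1.5 times the reported ones under the other probe set rules, normalisations, filters, moderation and array weights. With single arrays left out they ranged from 4098 to 4551 for the mean of both pairs (below, both pairs), 2690 to 3562 for A, 4457 to 5165 for B, 3272 to 4714 for A against B and 1844 to 2413 the same way. Of the counts per direction, genes lower with pair A went from 1376 to 2174 with array weights and 1782 with 75th percentile centring. Stricter thresholds are smaller by construction. With an adjusted p under 0.01 the genes changed the same way numbered 1478. With a 2-fold floor the counts were 258 for both pairs, 263 for pair A, 495 for pair B, 236 for A against B and 145 the same way, and with the treat test at a fold of 1.2 they were 1459, 998, 2123, 1277 and 636. Of the 26 gene lists, 10 were called for both pairs, 0 with an estimated correlation in camera and 21 with fry, which tests another hypothesis. With fry the immediate early genes were called lower (adjusted p = 0.039) while their median was 0.0045, so median and test differ in sign, and the cause was not tested. PHLDA1 with pair B went from -0.28 to 0.34 with the most variable probe set, which measures another probe set by construction.

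The replicate numbers did not pair the arrays: same-numbered arrays correlated between -0.13 and 0.104 in their deviations, 1 of 9 pairs was over 0.1, and 0 arrays correlated best with their own number in both other groups. Pair A arrays 2 and 3 did so among the pair B arrays (0.104 and 0.079). With the replicate block 4327 genes changed for both pairs, 3091 for A, 4893 for B, 3688 for A against B and 2092 the same way. The block ended the calls of KYNU with pair A (adjusted p = 0.061), of CASP8, GAPDH and MMP10 for both pairs (0.051, 0.058 and 0.070) and of CLDN4, MYC, PPM1D, ZMAT3 and GAPDH for A against B (0.078, 0.053, 0.060, 0.080 and 0.062). Calls of named genes lost without some single arrays were CDC20, CEP55, KYNU and SOS2 with pair A (adjusted p up to 0.0768, 0.149, 0.112 and 0.0515), CCNG2 and MYC with pair B (0.0766 and 0.0511), CASP8, ENO2, GAPDH, ISG15 and MMP10 for both pairs (0.0555, 0.141, 0.0975, 0.0685 and 0.126) and, for A against B, TAGLN, ZMAT3, PPM1D, GPR143, GAPDH, CDKN1B, MYC, CLDN4 and OCLN. The rise of CDK inhibitors with pair A lost its call without scrambled replicate 2 (adjusted p = 0.074), without the dimmest 40% of genes (0.069) and with array weights (0.054), and that of interferon-stimulated genes with pair A lost its call without the dimmest genes (adjusted p = 0.080). Over all alternatives and contrasts, fold changes of named genes lost their call in 112 cases, gained one in 123, reversed in 1 and kept their side of the threshold in 10669. Dim probe sets near background limit the fold sizes of genes such as NEFL and ZNF750 and the marker lists of other cell types, whose immune, endothelial and Merkel members had 0 genes brighter than the median gene.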

Other observations

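The tests of the 6 lists in this part were chosen only after the largest changes were seen, from classes that TAGLN, CLDN1 and ID3 belong to or that go with them, leaving out those genes, and the genes named here were named after their values were seen. Some contractile and tight junction genes rose over both pairs: MYLK, the myosin light chain kinase, by 1.66, TPM1, tropomyosin, by 1.27, CLDN4 by 1.84 and OCLN by 1.27. BCL6 and PIK3IP1, genes known to be induced by FOXO factors, rose by 1.21 and 1.13, NOTCH1 by 1.18, and the BMP and TGF-beta inhibitors BAMBI and SMAD7 by 1.32 and 0.93.

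As a hypothesis, these classes may move together with both siRNA pairs. For 25 actin cytoskeleton and contractile genes 12 rose and 1 fell (median 0.14, camera adjusted p = 5.2e-04; adjusted p = 0.11 with an estimated correlation). For 16 FOXO and quiescence genes 11 rose and 1 fell (median 0.57, camera adjusted p = 1.1e-04; adjusted p = 0.11 with an estimated correlation), with a lower median with pair A (0.38) than with pair B (0.68). Both had medians above 0 with each pair. The FOXO list holds CCNG2, whose fall by 0.79 had already been seen. Of 12 tight junction genes 6 rose over both pairs and 5 with pair B (adjusted p = 0.014 over both pairs; adjusted p = 0.11 with an estimated correlation), but their median was 0.20 with pair A and -0.03 with pair B, so a joint move stays open. The 17 BMP and TGF-beta genes (adjusted p = 0.069), 23 lysosome and autophagy genes (adjusted p = 0.069) and 13 Notch pathway genes (adjusted p = 0.13) did not pass, which does not show that they did not change. For the tight junction and BMP lists the values met the bounds written beforehand for no joint move (medians of opposite sign, and a median of 0.06 under 0.1). Those bounds ignored the spread of the members and were tightened after the results, so both classes are given as open and not as excluded.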
